A study of Mus musculus with 4 samples.

How the data were processed

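RNA from the quadriceps, the large muscle of the thigh, was sequenced in 4 libraries from 7-week-old mice, 2 from wild-type (WT) C57BL/6J mice and 2 from mice of the knockout strain B6.129S4-Vdrtm1Mbd/J, which lack a functional vitamin D receptor (gene Vdr). Per the labels' protocols, the mice were weaned at 21 days and had free access to chow and water, and muscles were flash frozen before total RNA was extracted. The kit is named in the labels as TruSeq in both places that mention it, once as an RNA kit of version 2 and once as a total RNA kit. The labels number the libraries of each group 1 and 2, do not say that these came from separate animals, and give no sex. P-values of single genes therefore measure only the spread between these libraries, which may be technical.

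The deposited files hold raw counts, whole numbers of reads per Ensembl gene, with 1 count column per library and no summary lines, as the values and the file layout show. Per the submitters' processing notes, Trimmomatic, STAR and DESeq2 were used with the mouse genome build GRCm38 (mm10); versions, parameters and the annotation release are not given in the sources used here. Each file lists 55573 gene IDs, of which 55480 (99.83%) matched GENCODE mouse release M21 on GRCm38, from which symbols and coordinates were taken, and 93 did not. A choice between strand columns had been planned and could not be made with 1 column. The column was checked for strand on overlapping genes. Of 457 genes that lie wholly under exons of the opposite strand, 119 had a count, and of 712 that lie wholly under exons of the same strand 1 had a count. The counts were thus strand-specific, and a gene that lies wholly under another on its own strand could hardly be measured. Members of families with near-identical copies, such as the globins and the Serpina3 genes, carry uncertain counts, since the handling of reads that map to several places is not given in the sources used here.

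Total counts were 10.79 M in WT replicate 1, 13.03 M in WT replicate 2, 21.34 M in knockout replicate 1 and 11.21 M in knockout replicate 2. Genes were kept by the filterByExpr function of edgeR 4.0.16 with its defaults (a minimum count of 10 and a minimum total of 15), which left 13076. Counts were scaled by the trimmed mean of M values (TMM), with factors from 0.9797 to 1.0485, and values are given as TMM-normalised CPM. Knockout and WT were compared with edgeR's quasi-likelihood F test with robust estimation in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment. A gene is called where the adjusted p is below 0.05. Standard errors of log2 fold changes were derived from the F statistic. Their median was 0.192 over the tested genes and 0.147 over those with a mean CPM of at least 10, and the common biological coefficient of variation was 13.59%. Where a group had 1 to 3 counts of a named gene, the ratio of the summed counts per group is given with an exact 95% interval (Clopper-Pearson), which covers counting error only, as do limits set by 3 counts.

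The choices of test, filter, scaling, gene lists and the rule for named genes were made before the data were examined. The rule names Vdr; the 12 called genes with the largest increase and the 12 with the largest decrease among those with a mean CPM of at least 2 and no overlap between the groups; in each list the 3 tested members with the smallest p and called members up to 6; and the 5 most abundant genes. Predicted genes found by the second part are counted and not named. The lists number 40, of which 11 cover fuel use, 14 cover muscle function, stress and signalling, 12 hold markers of other cell types and of sex, and 3 were included for handling and RNA quality. Of 778 symbols written, 777 matched a gene ID. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2). The correlation between genes was preset at 0.01, and p-values were adjusted over the 39 lists tested. These p-values set list members against the other genes and take genes as the units, so they measure no spread between animals. Camera with an estimated correlation and fry, a rotation test of whether the genes of a list move on balance in 1 direction, were alternatives. Camera with an estimated correlation called none of the 39 lists, and neither did fry. The list of fatty acid uptake and oxidation genes lost its call although its estimated correlation was 0.0122, close to the preset 0.01. Run on lists added later, fry called the X-linked genes known to escape inactivation (adjusted p = 0.0156). Camera with an estimated correlation did not call them (adjusted p = 0.315). Those p-values were adjusted over the added lists alone, and neither alternative was run on a planted list. How often they miss a shifted list is thus unknown, so their lack of calls decides nothing about a shift. A second count of called members is adjusted over the list alone. The share of called genes within 10, 20 and 30 Mb of Vdr was compared with the rest of the genome, since the knockout allele was made in 129S4 cells. The comparison used a one-sided Fisher's exact test, which also takes genes as the units.

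The alternatives were the size factors of DESeq2, library size alone, TMM without mitochondrially encoded genes and the 20 most abundant others, a minimum of 1 count in total, a CPM of at least 1 throughout a group, a block on replicate number, each library left out in turn, DESeq2 1.42.0, limma-voom, edgeR's legacy method, non-robust estimation, a test against a fold of 1.5 (glmTreat), an adjusted p below 0.1, and voom weights for the lists. A fit without genes of the X and Y chromosomes, and the fatty acid list without members that fat cells express strongly, were added after the data were seen. With 1 library left out, the lone library of a group is assumed to vary like the other group. An exact permutation test of 2 libraries against 2 gives a two-sided p of 0.333 at the smallest, so no permutation test of single genes was made.

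The tests were tried on data simulated for this comparison, with 5 runs of 12840 genes of which 200 were changed in each. In these, edgeR recovered 58.2% of genes changed 2-fold and 90.8% of those changed 4-fold, and 10.78% of its calls were false, above the nominal 5%. DESeq2 recovered 44.8% and 82.6% with 6.598% false, and limma-voom 54.8% and 89.6% with 10.42% false. With no list shifted, camera at the preset correlation called 1 list over the 5 runs of 39 lists each. The simulated genes were drawn independently of each other. Estimated correlations in the real data reached 0.264 for adipocyte markers, 0.281 for heat shock and 0.491 for interferon response genes. The runs thus do not check the preset correlation for such lists. A planted list of 20 genes shifted by 0.7 on the log2 scale was called in 5 of 5 runs. Camera with an estimated correlation and fry called 0 lists in the runs with none shifted, and were not run on the planted list. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.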

Results

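The data are gene counts from 4 RNA-seq libraries of mouse quadriceps at 7 weeks of age, 2 from WT mice and 2 from mice without a functional vitamin D receptor, a nuclear receptor that binds the active form of vitamin D. The design asks how gene expression in muscle differs without the receptor, and the series title names the choice of fuel in muscle as its subject. Total counts were 10.79 M and 13.03 M in the WT libraries and 21.34 M and 11.21 M in the knockout libraries, and between 19309 and 22226 genes had a count. The 5 most abundant genes were the mitochondrial ribosomal RNAs mt-Rnr2 (36.1% of counts on average) and mt-Rnr1 (7.30%), the small nuclear RNA Rn7sk (4.21%), the fast myosin heavy chain Myh4 (2.21%) and titin, Ttn (2.00%). None of these 5 was called between the groups (edgeR adjusted p from 0.144 to 0.981). The libraries of a group differed by more than counting noise. The chi-square per degree of freedom was 8.91 in WT and 16.1 in the knockout, so counts were not pooled in the edgeR tests. This excess does not show whether the libraries came from separate animals. The summed counts given below for Xist and Mymk have intervals that cover counting error only and leave this spread out. Values below are means ± SD of TMM-normalised CPM with n = 2 in each group, log2 fold changes are knockout over WT ± SE, and coordinates are on GRCm38.

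Vdr (ENSMUSG00000022479, chromosome 15, 97854425 to 97910630) had 5 and 0 counts in WT replicates 1 and 2 and 5 and 1 counts in knockout replicates 1 and 2. Without TMM scaling these stand for 0.463 and 0 CPM in WT and 0.234 and 0.089 CPM in the knockout, where 3 counts would be 0.278, 0.230, 0.141 and 0.268 CPM in the same order. A difference in Vdr was not detectable at this depth, and the allele is known to remove only a part of the gene that encodes the DNA-binding domain, so Vdr does not check the labels of these libraries.

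The 2 groups were of opposite sex by their sex-linked genes. Xist, the RNA that silences 1 X chromosome in female cells (chromosome X, 103460366 to 103483254), stood at 183 and 217 CPM in the WT libraries and at 0 and 0.256 CPM in the knockout libraries. Its summed counts were 4707 in WT and 3 in the knockout, a ratio of 2200 (95% interval 752 to 10700). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d reached 69.4 ± 9.02, 29.4 ± 5.25, 17.4 ± 2.13 and 13.3 ± 0.122 CPM in the knockout. In WT replicate 2 the same 4 genes had 0, 1, 0 and 0 counts. In WT replicate 1 they had 50, 21, 11 and 13 counts, together 6.96% of the knockout level. Of the 5 tested genes of the sex-linked list, Xist was called lower and none higher, and 3 were higher and 1 lower when adjusted over the list alone. The list had a median log2 fold change of 4.93 and a mean of 1.73 and was not called by camera (adjusted p = 0.056), but was called without WT replicate 1 (median 10.7) and without WT replicate 2 (3.87). Every difference between the groups below is therefore also a difference between libraries of opposite sex.

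**Figure D1:**
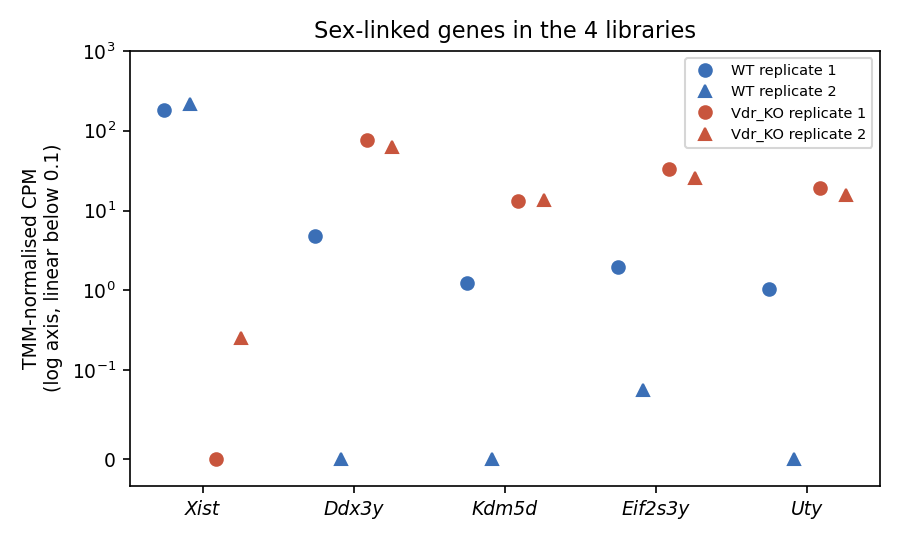
TMM-normalised CPM (log axis, linear below 0.1) of Xist and 4 Y-linked genes in each library, with blue points for WT, red points for the Vdr knockout and the replicate shown by the marker. Xist stood at 183 and 217 CPM in WT and at 0 and 0.256 CPM in the knockout, while the Y-linked genes were high in both knockout libraries, low in WT replicate 1 and at 0 or 1 count in WT replicate 2.

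In knockout muscle, camera with the preset correlation put fat-cell markers, lipid storage genes and, by less, fatty acid uptake and oxidation genes higher than in WT, and heat shock genes lower. With an estimated correlation none of these 4 lists was called (adjusted p = 0.576 for each), and of the 26 fatty acid genes 6 were called. Cfd, the fat-cell protease adipsin, rose from 400 ± 28.6 to 1874 ± 378 CPM and Adipoq, the fat-cell hormone adiponectin, from 79.3 ± 12.9 to 300.3 ± 0.883 CPM. Slc27a1, a fatty acid transporter, rose from 56.0 ± 3.52 to 137 ± 16.7 CPM. Hsp90aa1, an inducible chaperone, fell from 144 ± 36.4 to 40.1 ± 7.18 CPM. Genes of glycolysis, of the nuclear-encoded respiratory chain and of the fast contractile apparatus held no called member. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 265 of 13076 genes were called, 211 higher and 54 lower in the knockout, and 1829 genes had an unadjusted p below 0.05. Of the calls, 132 were at least 2-fold higher and 18 at least 2-fold lower, 253 were protein-coding, and 13 lay on the X chromosome and 0 on the Y. The groups did not overlap for any of the 265, as was so for 44.71% of all tested genes, where chance gives 33.33%. Without X-linked and Y-linked genes, a setting added after the data were seen, 251 genes were called. Leaving out 1 library kept 154 (without knockout replicate 1) to 196 (without WT replicate 2) of the 265 calls, and the count of lower genes was 90 without WT replicate 1.

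The rule names the 12 called genes with the largest increases. Hp, haptoglobin, which binds free haemoglobin (ENSMUSG00000031722, chromosome 8, 109575128 to 109579172), rose from 17.0 ± 3.72 to 102.6 ± 1.495 CPM (log2 fold change 2.60 ± 0.16, adjusted p = 8.94e-05). The protease inhibitors Serpina3n (2.31 ± 0.25) and Serpina3c (2.28 ± 0.25) and the iron carrier transferrin, Trf (2.20 ± 0.35), rose with it. Ifi27l2a, an interferon-inducible gene, rose from 55.5 ± 5.18 to 303 ± 29.2 CPM, and Acp5, an acid phosphatase of osteoclasts and macrophages, from 7.03 ± 0.429 to 33.0 ± 3.81 CPM. Hcar1, the lactate receptor of fat cells (2.36 ± 0.24), Mrap, an accessory protein of melanocortin receptors (2.16 ± 0.26), Cfd (2.23 ± 0.17) and the galactosyltransferase gene B3galt2 (2.53 ± 0.22) rose as well. Igkc, the constant region of immunoglobulin kappa, had 2 and 7 counts in WT and 98 and 35 in the knockout (3.33 ± 0.48). The adjusted p of these 11 genes lay between 8.81e-05 and 0.0119, and each was also called without each library in turn. Without WT replicate 2 the log2 fold change was 4.32 for Igkc, 3.12 for Trf and 2.78 for Mrap. The remaining 1 of the 12 is a predicted gene. Among lists of other cell types, camera at the preset correlation called fat-cell (median 1.70), neutrophil (3.98), red blood cell (1.04) and macrophage markers (0.22) higher. It called tendon markers lower (-0.48), and which cells the genes named above came from was not tested.

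Of the 12 genes that the rule names for the largest decreases, Xist comes first. Igfn1, a sarcomere-associated immunoglobulin and fibronectin domain protein (chromosome 1, 135953578 to 136006342), comes next and fell from 14.1 ± 2.35 to 2.06 ± 0.223 CPM (log2 fold change -2.78 ± 0.22, adjusted p = 0.000211). The chaperone genes Hsp90aa1 (-1.84 ± 0.20), Hsph1 (-1.70 ± 0.18), Hspa4l (-1.40 ± 0.16) and Hspb1 (-1.31 ± 0.14) fell too. The matrix-associated genes Ccn3 (-1.43 ± 0.17) and Mfap4 (-1.37 ± 0.18) fell as well. Dact2, a modulator of Wnt and TGF-beta signalling, fell (-1.69 ± 0.29), but its call was lost without knockout replicate 1 (-1.38). Sdf2l1, a cofactor of the endoplasmic reticulum, fell (-1.57 ± 0.28), and its call was lost without WT replicate 2 (-1.31), knockout replicate 1 (-1.65) or knockout replicate 2 (-1.52). The other 2 of the 12 are predicted genes.

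Most markers of fat cells were higher in both knockout libraries than in WT. Of 14 tested, 11 were called higher and none lower (12 and 0 when adjusted over the list alone), with a median log2 fold change of 1.70. Camera with the preset correlation gave an adjusted p = 6.02e-16, and the adjusted p = 0.576 with an estimated correlation. Cidec, a lipid droplet protein (chromosome 6, 113424634 to 113435760), rose from 59.3 ± 7.31 to 226 ± 24.6 CPM (1.93 ± 0.14), Adipoq (chromosome 16, 23146536 to 23158028) by 1.92 ± 0.14, Pck1, which makes glycerol backbones for fat, from 87.4 ± 6.67 to 300.9 ± 40.6 CPM (1.78 ± 0.14) and the hormone gene Retn from 32.4 ± 5.49 to 100.6 ± 2.07 CPM (1.63 ± 0.14). Adig, a small fat-cell protein, rose by 1.90 ± 0.15. The adjusted p of these 5 genes lay between 0.000163 and 0.000372. Lep, Cidea and Ucp1 did not pass the test, and Ucp1 ran the other way (-0.45), with 1.52 and 34.0 CPM in WT and 12.1 and 14.6 CPM in the knockout. The fat-cell list was called without each library in turn, with medians from 1.44 to 1.87.

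Genes of lipid synthesis and storage were higher with them. Of 23 tested, 8 were called higher and none lower (15 and 0 when adjusted over the list alone), 22 had a positive log2 fold change, and the median was 0.91 (camera adjusted p = 1.9e-12; adjusted p = 0.576 with an estimated correlation). The 3 lipases of stored and circulating fat rose. Pnpla2, the first lipase of lipolysis (chromosome 7, 141455198 to 141460743), rose from 86.9 ± 6.70 to 212 ± 11.2 CPM (1.29 ± 0.13), Lipe, hormone-sensitive lipase, from 48.6 ± 8.11 to 146 ± 29.4 CPM (1.59 ± 0.17) and Lpl, lipoprotein lipase, from 248 ± 23.0 to 560 ± 105 CPM (1.17 ± 0.16). Dgat2 (1.34 ± 0.15) and Dgat1 (1.31 ± 0.18), which add the last acyl chain of triglycerides, and the droplet coat gene Plin4 (0.93 ± 0.12) rose as well. The adjusted p of these 6 genes lay between 0.00093 and 0.00454, and their calls stayed without each library in turn.

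Genes of fatty acid uptake and beta-oxidation moved in the same direction by less. Of 26 tested, 6 were called higher and none lower (19 and 0 when adjusted over the list alone), 25 had a positive log2 fold change, and the median was 0.45 (camera adjusted p = 4.06e-11; adjusted p = 0.576 with an estimated correlation). Slc27a1 (chromosome 8, 71568882 to 71587302; 1.29 ± 0.14), Acsl1, which activates fatty acids to acyl-CoA (1.12 ± 0.16), and Cd36, a fatty acid translocase (171 ± 0.0127 against 335 ± 4.73 CPM; 0.97 ± 0.12), rose with adjusted p from 0.00129 to 0.00602, and fat cells express these 3 strongly. Without 5 members of which this is known, a setting added after the data were seen, 3 of 21 members were called and the median was 0.43. Those 3 were Slc25a20, the carnitine and acylcarnitine carrier of the inner mitochondrial membrane, which rose from 30.3 ± 0.509 to 51.3 ± 4.93 CPM (0.76 ± 0.13), and the matrix enzymes Acaa2 (0.61 ± 0.13) and Hadh (0.57 ± 0.12). Slc25a20 was not called without knockout replicate 1 (0.65). Acaa2 was not called without WT replicate 1 (0.53), knockout replicate 1 (0.52) or knockout replicate 2 (0.70), and Hadh was not called when any 1 library was left out (0.51 to 0.63). The fat-cell markers, at a median of 1.70, were higher in the same 2 libraries.

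**Figure D2:**
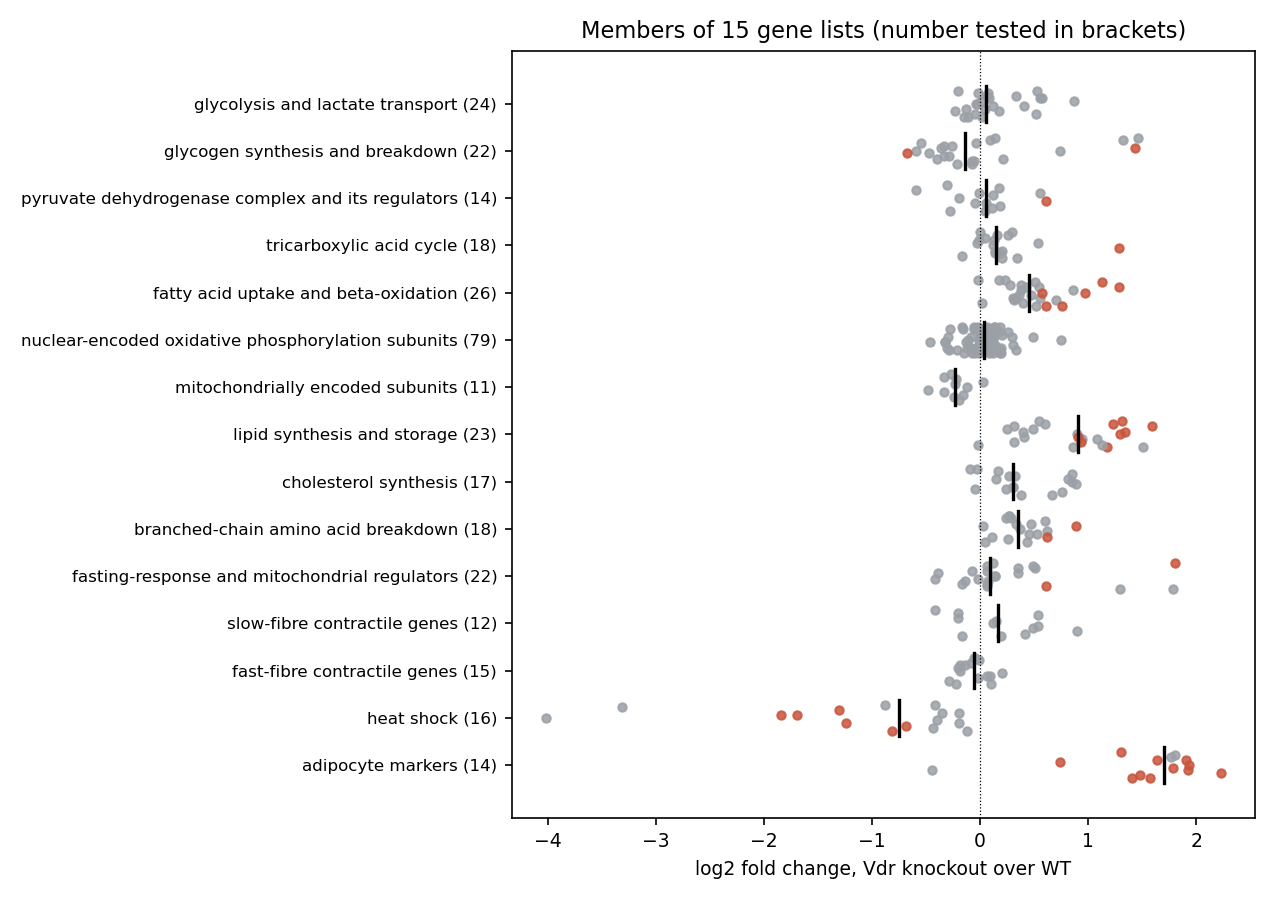
Log2 fold change (knockout over WT) of the tested members of 15 gene lists, with the number tested in brackets, 1 point per gene, red points for genes called by edgeR and black bars for list medians. The medians run from -0.75 for heat shock genes to 1.70 for adipocyte markers, with fatty acid genes at 0.45 and glycolysis at 0.06.

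Genes of glycolysis, glycogen, pyruvate dehydrogenase and the nuclear-encoded respiratory chain moved little or without a common direction. Glycolysis and lactate transport had no called gene among 24 (1 higher when adjusted over the list alone), a median of 0.06 and a camera adjusted p = 0.252, although it was called without WT replicate 1 (median 0.23) and had a median of -0.07 without WT replicate 2. Of 22 glycogen genes, 1 was called higher and 1 lower (3 and 3 adjusted over the list alone). Their median was -0.14 and their mean 0.03, and camera put the list lower (adjusted p = 0.27). The median ran from -0.31 without WT replicate 2 to -0.03 without WT replicate 1, and the list was called in none of the 4 runs. Ppp1r3c, which directs a phosphatase to glycogen, rose from 98.9 ± 20.1 to 267 ± 86.6 CPM (1.44 ± 0.25), and Phka1, the X-linked muscle subunit of phosphorylase kinase, fell from 382 ± 55.8 to 238 ± 7.47 CPM (-0.68 ± 0.14). Ppp1r3c was not called without WT replicate 2 (1.24), and Phka1 was not called without WT replicate 1 (-0.52), knockout replicate 1 (-0.72) or knockout replicate 2 (-0.65). Of the pyruvate dehydrogenase list, 1 of 14 members was called (1 adjusted over the list alone; median 0.05, camera adjusted p = 0.773). Its median was 0.13 without WT replicate 1 and turned negative without WT replicate 2 (-0.03) or knockout replicate 1 (-0.03). It was Pdk4, the kinase that shuts pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), which rose from 89.7 ± 7.02 to 137 ± 5.54 CPM (0.61 ± 0.12, adjusted p = 0.0345) and was not called without WT replicate 2 (0.53), knockout replicate 1 (0.65) or knockout replicate 2 (0.57). The nuclear-encoded respiratory chain had no called gene among 79 and none adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.581), which was 0.11 without WT replicate 1 and -0.003 without WT replicate 2.

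Of 18 genes of the tricarboxylic acid cycle list, 1 was called (2 adjusted over the list alone; median 0.15, camera adjusted p = 0.022; adjusted p = 0.601 with an estimated correlation). It was Pcx, pyruvate carboxylase, which refills the cycle and is abundant in fat cells, and it rose from 84.7 ± 18.5 to 207 ± 3.38 CPM (1.29 ± 0.16, adjusted p = 0.00238). The call of the list was lost without WT replicate 2 (median 0.12) or knockout replicate 1 (0.08), and the median was 0.22 without knockout replicate 2. Breakdown of branched-chain amino acids had 18 of 18 tested genes with a positive log2 fold change, 2 called higher and none lower (8 and 0 adjusted over the list alone), and a median of 0.35 (camera adjusted p = 8.1e-05; adjusted p = 0.576 with an estimated correlation), which was 0.19 without knockout replicate 1. Fat-cell markers (median 1.70, 11 of 14 called) were higher in the same 2 libraries. Bcat2, the mitochondrial aminotransferase, rose by 0.89 ± 0.18, a call lost without WT replicate 2 (0.80) or knockout replicate 1 (0.59). Pccb, a subunit of propionyl-CoA carboxylase, rose by 0.62 ± 0.12, a call lost without WT replicate 2 (0.54), knockout replicate 1 (0.63) or knockout replicate 2 (0.62). Cholesterol synthesis had no called gene among 17 (1 adjusted over the list alone), a median of 0.30 and a camera adjusted p = 0.00178 (adjusted p = 0.576 with an estimated correlation), a call lost without knockout replicate 1 (0.15). Mitochondrially encoded subunits had no called gene among 11 (1 lower adjusted over the list alone) and a median of -0.23 (camera adjusted p = 0.0109; adjusted p = 0.576 with an estimated correlation), a call lost without WT replicate 1 (-0.16) or knockout replicate 2 (-0.10). Their median was -0.40 without knockout replicate 1. Of 22 fasting-response and mitochondrial regulators, 2 were called higher (4 adjusted over the list alone; median 0.09, camera adjusted p = 0.0531). Pdk4 was among them. This list was called without WT replicate 1 (0.17) or knockout replicate 2 (0.19) and stood at 0.03 without knockout replicate 1.

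Heat shock genes were lower in both knockout libraries. All 16 tested had a negative log2 fold change, 6 were called lower and none higher (11 and 0 adjusted over the list alone), and the median was -0.75 (camera adjusted p = 4.06e-11; adjusted p = 0.576 with an estimated correlation). Hsp90aa1 (chromosome 12, 110690605 to 110702728) had an adjusted p = 0.00188, Hsph1, a nucleotide exchange factor, fell from 64.6 ± 18.0 to 19.9 ± 0.315 CPM (adjusted p = 0.00129), and Hspb1, a small heat shock protein, from 77.8 ± 8.11 to 31.4 ± 4.19 CPM (adjusted p = 0.00134). Dnaja1, a J-domain co-chaperone, fell by 1.24 on the log2 scale. Bag3, a co-chaperone of muscle autophagy (-0.81 ± 0.13), was not called without knockout replicate 2 (-0.81), and Hsp90ab1 (-0.68 ± 0.14) was not called without WT replicate 1 (-0.53), knockout replicate 1 (-0.71) or knockout replicate 2 (-0.65). The most inducible members, Hspa1a and Hspa1b, had 845 and 1198 counts in WT replicate 1, 434 and 654 in WT replicate 2, 177 and 151 in knockout replicate 1 and 28 and 28 in knockout replicate 2, and did not pass the test (adjusted p = 0.399 and 0.298). These 2 were chosen after their values were seen, and as near-identical copies they share reads.

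**Figure D3:**
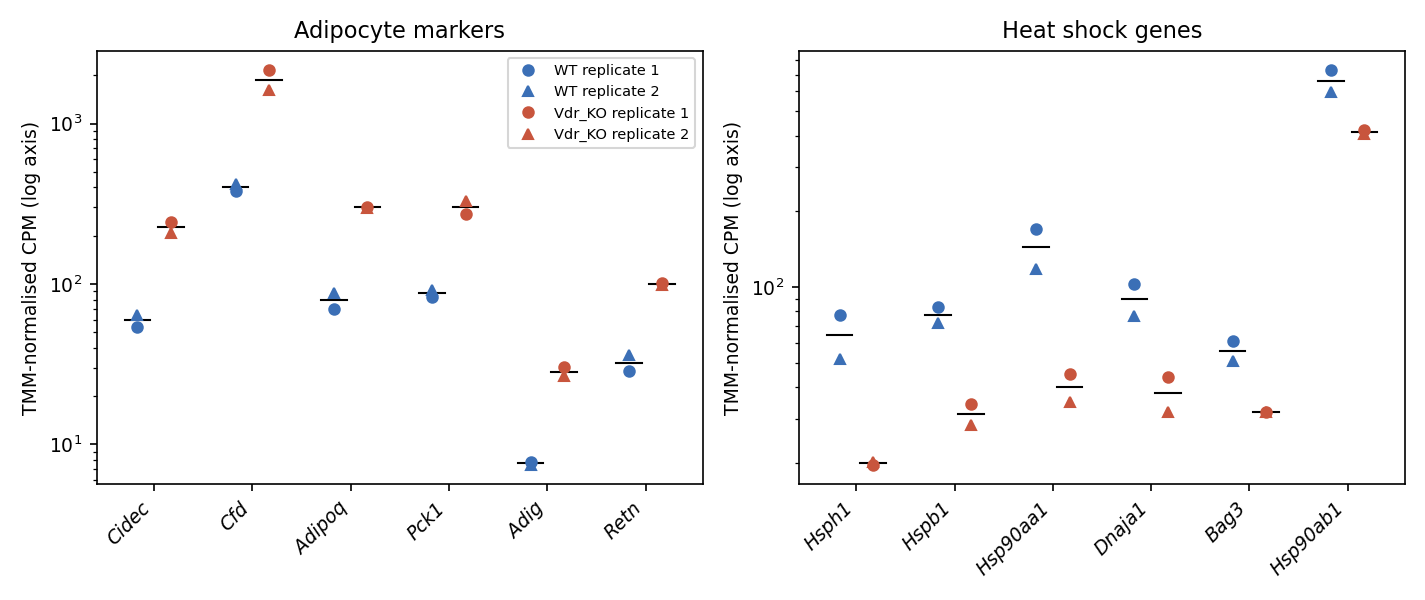
TMM-normalised CPM (log axis) of 6 adipocyte markers and 6 heat shock genes in each library, with blue points for WT, red points for the Vdr knockout, the replicate shown by the marker and horizontal bars for group means. Both knockout libraries lay above both WT libraries for the 6 adipocyte markers and below them for the 6 heat shock genes.

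Contractile genes showed no common change. No slow-fibre gene among 12 and no fast-fibre gene among 15 was called, over all genes or adjusted over the list alone, with medians of 0.17 and -0.06 (camera adjusted p = 0.771 and 0.298). The fast-fibre median was -0.12 without WT replicate 2 and -0.003 without WT replicate 1. Camera put the slow-fibre list lower against its positive median and mean (0.19). The slow-fibre median turned with the knockout library kept: it was -0.53 without knockout replicate 1 and 0.66 without knockout replicate 2, and the list was called both times. Of 29 calcium handling genes, 2 were called higher and none lower (2 and 0 adjusted over the list alone) against a median of -0.14 (camera adjusted p = 0.0459; adjusted p = 0.576 with an estimated correlation), and the list was not called when any 1 library was left out (-0.17 to -0.09). S100a1, a calcium sensor of the calcium release channel, rose from 50.5 ± 0.16 to 80.8 ± 5.97 CPM, a call lost without WT replicate 1 (0.68) or knockout replicate 2 (0.60). Sln, sarcolipin, an inhibitor of the calcium pump, rose from 1.24 ± 0.0117 to 3.77 ± 1.12 CPM, a call lost without WT replicate 1 (1.63), WT replicate 2 (1.65) or knockout replicate 1 (1.25). Of 12 satellite cell and myogenesis genes, 1 was called lower (1 adjusted over the list alone; median -0.29, camera adjusted p = 0.0106; adjusted p = 0.576 with an estimated correlation), and the list was not called without knockout replicate 2 (-0.27) and stood at -0.48 without knockout replicate 1. It was Mymk, which drives fusion of myoblasts, with 44 summed counts in WT and 2 in the knockout, a ratio of 30.8 (95% interval 8.05 to 263), and its call was lost without WT replicate 2 (-4.15) or knockout replicate 1 (-4.29). Of 15 denervation and neonatal genes, 1 was called higher (2 adjusted over the list alone; median -0.32, mean -0.18, camera adjusted p = 0.136), and the list was called without WT replicate 1 (-0.44) and stood at -0.09 without WT replicate 2. It was Cdkn1a, a cell cycle inhibitor that is also on the atrophy and vitamin D lists, which rose from 5.69 ± 0.00726 to 11.2 ± 0.732 CPM and was not called without WT replicate 1 (0.98), WT replicate 2 (0.98) or knockout replicate 1 (0.90).

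Of 6 tested genes of the vitamin D pathway, Cdkn1a alone was called (1 adjusted over the list alone), and the median was 0.30 (camera adjusted p = 0.0251; adjusted p = 0.576 with an estimated correlation), a call lost when any 1 library was left out (0.23 to 0.31). The receptor partner Rxrg had a log2 fold change of 0.36 ± 0.15 and the hydroxylase gene Cyp27a1 one of 0.23 ± 0.15, neither of them called. Of 25 atrophy genes, 2 were called higher and none lower (5 and 3 adjusted over the list alone). Their median was -0.06, against a mean of 0.14 and a higher direction by camera (adjusted p = 0.786), and the median turned positive without WT replicate 1 (0.10) or knockout replicate 2 (0.04). The 2 were Cdkn1a and Fbxo21, a ubiquitin ligase subunit, which rose from 11.5 ± 0.663 to 26.5 ± 2.26 CPM. No autophagy and lysosome gene among 24 was called, over all genes or adjusted over the list alone (median 0.02, camera direction lower, adjusted p = 0.704), with a median of -0.09 without knockout replicate 1. Of 21 genes of insulin and growth factor signalling, 1 was called (2 adjusted over the list alone; median 0.19, camera adjusted p = 0.0952), and the list was called without WT replicate 1 (0.23) or knockout replicate 2 (0.26) and stood at 0.08 without knockout replicate 1. It was Igfbp4, a binding protein of insulin-like growth factors, which rose by 0.60 ± 0.12 and was not called when any 1 library was left out (0.55 to 0.65). Of 17 stress response genes, 2 were called higher and 1 lower (2 and 3 adjusted over the list alone; median -0.13, mean 0.04, camera direction lower, adjusted p = 0.467), and the median was -0.07 without WT replicate 1. The serine synthesis genes Phgdh, which rose from 6.10 ± 1.02 to 14.9 ± 0.702 CPM, and Psat1 (1.44 ± 0.25; 1.15 and not called without knockout replicate 1) were the higher ones, and Sdf2l1 was the lower one. Of 19 antioxidant genes, 3 were called higher and none lower (6 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 0.0289; adjusted p = 0.576 with an estimated correlation), a call lost without WT replicate 2 (0.14) or knockout replicate 1 (0.12). Catalase, Cat, rose from 73.3 ± 7.94 to 158 ± 26.9 CPM and Gpx3 from 55.1 ± 12.9 to 126 ± 24.7 CPM, in the same 2 libraries in which fat-cell markers (median 1.70) were higher. Gpx1 rose by 0.73 ± 0.15 and was not called without WT replicate 1 (0.61) or knockout replicate 1 (0.52).

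All 20 tested interferon response genes had a positive log2 fold change, 1 was called (2 adjusted over the list alone), and the median was 0.62 (camera adjusted p = 5.44e-06; adjusted p = 0.576 with an estimated correlation), which fell to 0.25 without knockout replicate 1. The called member was Ifi27, which rose from 27.7 ± 5.35 to 54.4 ± 5.16 CPM. Of 25 extracellular matrix genes, 1 was called lower (1 adjusted over the list alone; median -0.09, camera adjusted p = 0.0794), and the list was called without WT replicate 1 (-0.14) and stood at -0.05 without WT replicate 2. It was Ccn2, connective tissue growth factor, which fell from 61.0 ± 4.12 to 31.3 ± 2.63 CPM. Of 23 immediate-early genes, 2 were called higher and none lower (2 and 0 adjusted over the list alone; median 0.49, camera adjusted p = 0.0253; adjusted p = 0.624 with an estimated correlation). The call of that list was lost without WT replicate 2 (0.56), and the median was -0.07 without knockout replicate 1. Zfp36, which destabilises messenger RNAs, rose from 6.79 ± 0.446 to 15.7 ± 0.984 CPM, and Dusp1, a phosphatase of MAP kinases, rose by 0.63 ± 0.12, a call lost without WT replicate 1 (0.63), WT replicate 2 (0.62) or knockout replicate 2 (0.57). Of 17 clock genes, 1 was called lower (1 higher and 2 lower adjusted over the list alone; median -0.18, camera adjusted p = 0.115), and the list was called without knockout replicate 2 (-0.45) and stood at -0.09 without knockout replicate 1. It was Nr1d2, a repressor of the clock, which fell from 132 ± 9.43 to 82.6 ± 12.5 CPM and was not called without WT replicate 1 (-0.60) or knockout replicate 1 (-0.54). No gene among 47 cytosolic ribosomal proteins was called, over all genes or adjusted over the list alone (median 0.07, camera adjusted p = 0.178; 0.02 without WT replicate 2).

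Some lists of other cell types were called at the preset correlation and others were not. Of 5 red blood cell genes, 2 were called higher (5 adjusted over the list alone; median 1.04, camera adjusted p = 0.000212; adjusted p = 0.576 with an estimated correlation). The beta globin gene Hbb-bt rose from 23.4 ± 0.246 to 48.5 ± 13.1 CPM, and Alas2, the first enzyme of haem synthesis in red cells, rose by 1.16 ± 0.23, a call lost without WT replicate 2 (1.00) or knockout replicate 1 (0.91). Of 3 tested neutrophil markers, Mmp9 was called higher (1 adjusted over the list alone; median 3.98, camera adjusted p = 0.00287; adjusted p = 0.576 with an estimated correlation). Mmp9 rose from 2.28 ± 0.13 to 7.42 ± 1.94 CPM, a call lost without knockout replicate 1 (1.41), and without that library too few members were left to test the list, while its median was 6.43 without WT replicate 2. Of 10 tendon genes, 1 was called lower (3 adjusted over the list alone; median -0.48, camera adjusted p = 0.00058; adjusted p = 0.576 with an estimated correlation), and the list was not called without knockout replicate 2 (-0.15) and stood at -0.86 without knockout replicate 1. It was Cilp2, a cartilage layer protein, which fell from 27.8 ± 4.78 to 14.0 ± 2.63 CPM and was not called without WT replicate 1 (-0.79) or knockout replicate 2 (-0.81). Of 12 macrophage genes none was called, over all genes or adjusted over the list alone, and the median was 0.22 (camera adjusted p = 0.0288; adjusted p = 0.576 with an estimated correlation), a call lost without WT replicate 1 (0.12), knockout replicate 1 (0.23) or knockout replicate 2 (0.24). Without WT replicate 2 it was 0.38. Endothelial (13 tested, median -0.13, camera adjusted p = 0.23), fibro-adipogenic progenitor (13, -0.30, 0.114), smooth muscle and pericyte (11, -0.07, 0.103) and Schwann cell genes (11, 0.10, 0.339) had no call over all genes, with 1 higher endothelial, 3 lower progenitor and 1 lower smooth muscle gene adjusted over the list alone. The smooth muscle list was called without knockout replicate 1 (-0.29) and stood at -0.01 without knockout replicate 2, the Schwann cell list stood at 0.22 without WT replicate 1 and -0.002 without WT replicate 2, and the progenitor list at -0.17 without WT replicate 2. Of the lymphocyte list 1 gene, Ighm, could be tested (0.10 ± 0.13, not called). Bone and cartilage genes had no call among 7, over all genes or adjusted over the list alone (median 0.56, mean 2.15, camera adjusted p = 0.0673). That list was called without WT replicate 2 (median 1.37) or knockout replicate 2 (1.55) and had a median of -0.28 without knockout replicate 1.

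In all, camera with the preset correlation called 18 of the 39 lists tested, 13 higher and 5 lower, while camera with an estimated correlation called 0 and fry called 0. Of the 18, 7 were called at the preset correlation without each library in turn: fatty acid uptake and beta-oxidation, lipid synthesis and storage, branched-chain amino acid breakdown, heat shock, interferon response, adipocyte markers and red blood cell genes.

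Around Vdr itself, where sequence of the donor strain can remain next to a bred-in allele, 8 genes within 20 Mb on chromosome 15 were called. Tst, a sulfurtransferase gene, rose from 13.6 ± 0.251 to 38.1 ± 4.27 CPM and Tspo, a mitochondrial membrane protein gene, from 24.9 ± 1.43 to 48.9 ± 1.68 CPM, and Mfng, Pnpla3, Abcd2, Tuba1c and Csad rose too, while Igfbp6 fell from 77.7 ± 2.41 to 52.7 ± 2.46 CPM. The 8 calls among 278 tested genes are 2.88%, against 2.01% elsewhere in the genome (one-sided Fisher's exact test, p = 0.204). Within 10 Mb 4 of 154 genes were called (2.60%, exact p = 0.38) and within 30 Mb 12 of 354 (3.39%, exact p = 0.0571). Within 10 and 20 Mb, the share of called genes lay below that elsewhere without WT replicate 1, WT replicate 2 or knockout replicate 2. It lay above that elsewhere without knockout replicate 1. These 8 genes are named because of their position, outside the rule, after their values were seen.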

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

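The fit without genes of the X and Y chromosomes and the fatty acid list without members that fat cells express strongly were tests chosen after the result was seen. With all libraries kept, the count of called genes stayed between 212 (limma-voom) and 346 (replicate block), but for 3 settings. A minimum of 1 count in total gave 476 calls (355 higher, 121 lower), an adjusted p below 0.1 gave 445 (331 and 114), and testing against a fold of 1.5 gave 71 (60 and 11); the looser filter tests more genes, the looser threshold admits more and the fold test admits fewer by construction. With library size only, 35 genes were lower and 236 higher; the median of all genes then stood at 0.047, and the cause was not tested further. No called gene changed sign in any setting. Without 1 library, 216 to 332 genes were called, of which 39 (without knockout replicate 1) to 90 (without WT replicate 1) were lower; the lone library is assumed to vary like the other group. Of 68 named called genes, 43 were called without each library in turn and 31 under every alternative.

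Camera with an estimated correlation called 0 of the 39 lists and fry called 0. Of lists added later, fry called the X-linked genes known to escape inactivation (adjusted p = 0.0156). Camera with an estimated correlation did not (adjusted p = 0.315). Neither was run on a planted list, so their lack of calls among the 39 decides nothing about a shift. A list's median does not depend on these tests, so lists that lost their call kept, among others, 0.147 (tricarboxylic acid cycle), 0.45 (fatty acid), -0.233 (mitochondrially encoded), 0.907 (lipid synthesis), 0.305 (cholesterol), 0.35 (branched-chain amino acids), -0.748 (heat shock), 0.625 (interferon) and 1.7 (adipocyte). The fasting-response list was called with a minimum of 1 count in total (0.128) and with voom weights (0.094), which called 25 lists in all.

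Leaving out 1 library moved the medians of the glycolysis list from -0.067 (without WT replicate 2) to 0.231 (without WT replicate 1, called), tricarboxylic acid cycle 0.084 to 0.223, mitochondrially encoded subunits -0.395 to -0.1, cholesterol synthesis 0.146 to 0.452 and fasting response 0.028 to 0.186. In these 4 lists the ends are those without knockout replicates 1 and 2. Slow-fibre genes turned from -0.531 without knockout replicate 1 to 0.663 without knockout replicate 2, and immediate-early genes from -0.07 to 0.573 in the same order; the cause was not tested.

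In the replicate block, same-numbered libraries were treated as pairs. Their deviations correlated by 0.039 across genes, which shows no strong shift shared by same-numbered libraries. It does not show whether they were paired. The block called 346 genes, lost the calcium handling list and gained the bone and cartilage and the sex-linked lists; it changed no other call of a list. The unstranded column or the other strand column was not run, since each library has 1 count column. Without knockout replicate 1 the neutrophil list had too few tested members. Depth limits Vdr itself, with 0 to 5 counts per library.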

Other observations

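All tests in this part were chosen after the result was seen except those of fat RNA within the groups, of knockout replicate 2 as a source of reads and of androgen-responsive genes.

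Several genes of antigen presentation by MHC class I were called higher in knockout muscle. Of 14 such genes, picked after values were seen, 7 were called higher and none lower: H2-K1 (log2 fold change 0.95), H2-D1 (0.82), B2m (0.84), the peptide transporters Tap1 (1.29) and Tap2 (0.87), the immunoproteasome subunit Psmb8 (1.26) and the class I regulator Nlrc5 (1.38). No test of the group is given, since it was picked for its values. Without knockout replicate 1, H2-K1 alone of the 7 kept its call (B2m at 0.71, Nlrc5 at 1.25). Without WT replicate 1, H2-D1 (0.67) and Tap2 (0.77) lost theirs, and without WT replicate 2 Tap1 did (1.14).

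Some libraries stood apart in genes that were not called and were picked after their values were seen. Knockout replicate 1 had 39.2 CPM of the bone gene Ibsp against 3.16 in knockout replicate 2, where the WT libraries had 1 and 0 counts. It also had 60.4 against 17.1 CPM of the cartilage collagen Col2a1 and 9.13 against 1.11 CPM of the neutrophil gene S100a8. Both genes kept a positive log2 fold change in every setting, also without knockout replicate 1 (at least 1.57 for Col2a1 and 1.66 for S100a8). Ucp1, of brown fat, had 16 counts in WT replicate 1, 436 in WT replicate 2 and 254 and 171 in knockout replicates 1 and 2.

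The first pattern is the rise of fat-cell and lipid genes. A lower share of muscle fibre RNA would raise other cell types alike, but the highest median among 6 of their lists was 0.224 (macrophages; SD 0.319 over members) against 1.70 in fat-cell markers (SD 0.664), and the lowest was -0.48 (tendon; SD 0.296), which argues against it as the whole cause. These 6 lists were picked after the medians were seen, and 3 lists with higher medians were left out of the test, of red blood cells (1.04), neutrophils (3.98) and bone and cartilage (0.56). More fat tissue RNA in the knockout libraries may explain the pattern and cannot be told apart from a change in fibres: the genes called higher outside the fat-cell list moved with the fat-cell markers between the WT libraries (median 0.119, markers 0.279, random sets -0.06 to 0.016), and in the knockout libraries, where the markers hardly differed (0.003), by -0.065 (random sets -0.043 to 0.041). The fatty acid list had a median of 0.427 without 5 members that fat cells express strongly, which decides nothing, since it would stay at 0.381 without its 5 highest members, and a change inside muscle fibres stays open, untested.

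The second pattern is the difference in sex-linked genes. The 4 Y-linked genes of WT replicate 1 stood at 1 shared ratio to the knockout level within counting error (exact conditional test by simulation, p = 0.684), which is consistent with RNA or reads of a male library mixed into it; knockout replicate 1 as their source is argued against by 2 genes high in that library alone, which had 0.0598 of the counts expected (2 against 33.42), and 0 genes were high in knockout replicate 2 alone, so that source was not testable. The 4 tested X-linked genes known to escape inactivation were all lower in the knockout (highest log2 fold change -0.355), in line with libraries from mice of opposite sex. Androgen-responsive genes had a median of 0.125, inside the bound of 0.15 written beforehand as speaking against an effect of sex. That bound was wrong for members that run from -0.73 (Mylk4) to 0.92 (Fkbp5). The median was 0.41 without WT replicate 1 and -0.06 without WT replicate 2, so this list decides nothing. How much of the other differences follows sex, how much the strain and how much the receptor cannot be told apart with these 4 libraries.

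The third pattern is the fall of heat shock genes. It did not rest on 1 library, since the median nearest 0 with 1 library left out was -0.518 (without WT replicate 1). A different time of day at dissection could contribute and cannot be told apart: clock genes of the Arntl phase had a median of 0.334 and those of the opposite phase -0.389, and the arms lay 0.854 apart in knockout replicate 1 and 0.574 in knockout replicate 2, where heat shock medians were -0.578 and -0.756. Against it, the opposite-phase median was -0.17 without knockout replicate 1 while the heat shock median stayed at -0.77. Nr1d1 also stood at 49.9 CPM in knockout replicate 2 (42.6 and 43.2 in WT, 5.85 in knockout replicate 1). The Arntl-phase median, however, was still 0.41 without knockout replicate 1. Its genes were mixed in knockout replicate 2: Arntl, Clock and Npas2 (3 to 14 counts per library) lay above both WT libraries, and Nfil3 and Cry1 below both. Dissection times are not given in the sources used here, and genotype and sex stay open as untested.

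The 4 libraries allow 3 splits into 2 and 2, of which 1, the real one, gave as many calls (265; the highest other gave 0), too few splits for a share under 0.05.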
